A study of Mus musculus with 2 samples.

How the data were processed

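Testis RNA of 12-week-old mice was measured by sequencing in 2 samples, 1 per genotype, and the labels do not say whether a sample pools animals. Per the submitters' processing notes, cutadapt 2.7, FastQC 0.11.8 and HISAT2 2.1.0 were used with the mouse genome build GRCm38; the counter, the annotation release and the strand setting are not given in the sources used here. The authors deposited gene expression as FPKM, with 1 column per genotype, beside a gene length in bases. The authors' deposited table of the comparison gives a log2 fold change, a p-value and an adjusted p-value per gene; the test is not given in the sources used here. All genes in the authors' deposited table had an adjusted p of at most 0.00900 and an absolute log2 fold change of at least 1.00. A further 2 per-sample columns of that table were not used. One row of the matrix, with no gene, is not analysed here.

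Genotypes were taken from the sample labels. Exon lengths, gene overlaps and transcript GC content came from GENCODE M21 on the same build, GRCm38, with an exon length for 53705 of the 53800 genes and GC content for 15533 of the 15560 genes at the expression floor. GC content was that of the longest transcript of a gene. FPKM times the merged exon length was divided by the value of 1 fragment, found from the most frequent low value, and a result within 0.01 of a whole number was taken as a fragment count. This held for 94.7% of values above 0 in the library labelled Chd2+/- and 94.8% in the library labelled Chd2+/+. In a gene with 1 kb of exon, 1 fragment was worth 0.0397 FPKM in the former and 0.0358 FPKM in the latter. The whole fragments summed to 24296523.0 and 24623291.0, over the genes that gave whole numbers. Folds are ratios of FPKM; where both libraries gave whole fragments, they carry an exact (Clopper-Pearson) 95% interval, and a library at 0 was set to a floor of 3 fragments. A gene counts as sharing exon positions where an exon overlaps, on either strand, one of a gene with at least 10 fragments.

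With 1 library per genotype no test between genotypes was made and no p-value was computed. Before the data were examined, these choices were made: log2(FPKM + 1), genes with at least 1 FPKM in either library, a cut of 2-fold, 33 gene lists, and the alternatives. Each list with at least 5 measured members, and each chromosome, was described by the percentile of its median log2 ratio among 10000 random lists of the same size, matched in 10 bins of mean expression, and called outside beyond the central 95%. The lymphocyte (4 members), epididymis (2) and interferon (3) lists were too small. In a simulation on the 15560 genes, each gene got independent noise of SD 0.4 on the log2 scale and a trend with mean expression. There 96 of 100 lists of 20 genes shifted by 0.5 lay above the range, and 6 of 100 unshifted lists lay outside it. Unshifted and random lists were drawn from all genes, so they could hold shifted ones. A shift of 0.5 is larger than most list medians given here, and lists of fewer genes were not simulated. Genes of a real list can move together, which was not simulated, so 6 of 100 is not the rate of chance calls for real lists.

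Genes were named by a rule: Chd2; the 12 highest and 12 lowest by log2 fold change in the authors' deposited table with at least 1 FPKM, the same direction in FPKM and an established symbol; up to 4 members of each list, first those in the authors' deposited table and then by size of the ratio; and 10 genes chosen by name, among them Gfra1, Zbtb16, Kit, Stra8, Sycp3 and Star. Some of the genes that the rule names are not printed here. Other list members (such as Id4, Etv5, Insl3 and Cyp11a1), Kctd12 and the overlapping genes were named after their values were seen. The alternatives were pseudocounts of 0.1 and 0.01, rescaling to the same median ratio or to TPM, no floor or 5 FPKM, a cut of 1.5-fold, unmatched lists and 20 bins. Scaling by the sum of whole fragments and removal of the trend with GC content (a local regression over a fraction of 0.3 of genes) were added after seeing the data. So were protein-coding genes only and leaving out genes that share exon positions. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.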

Results

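Testis RNA from 12-week-old C57BL/6 mice was sequenced for 2 genotypes, Chd2+/+ and Chd2+/-, with 1 sample of each. The series title asks how CHD2, a chromatin-remodelling ATPase of the chromodomain helicase family, bears on spermatogonial self-renewal, chromatin and mRNA stability. Expression was given as FPKM, a fragment count scaled by gene length and library total, for 53800 genes. In the library labelled Chd2+/-, 26306 genes had a value above 0 and 14826 reached 1 FPKM, against 26639 and 14904 in the library labelled Chd2+/+. Multiplied by exon length, the FPKM values stepped in whole fragments, which put the scaling total at 25180100.0 fragments for the library labelled Chd2+/- and 27907876.0 for the library labelled Chd2+/+. Because each genotype has a single library, no difference below has a replicate check, and every 95% interval of a fold is an exact binomial interval that covers counting error only.

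Chd2 itself (ENSMUSG00000078671, GRCm38 chromosome 7, 73426638 to 73541830, minus strand, protein-coding) was not lower in the library labelled Chd2+/-. Its level was 1.68 FPKM there, from 605 fragments, and 1.59 FPKM in the library labelled Chd2+/+, from 636 fragments. The ratio was 1.05-fold (95% interval 0.942 to 1.18), and the gene is not in the authors' deposited table. Its exons overlap those of 1810026B05Rik and Gm44686, so its value carries that uncertainty. On the scale of log2(FPKM + 1) the difference was 0.05, and it became -0.03 when FPKM was rescaled to TPM, which has the same sum in each library. The gene-level value therefore gives no support for the genotype label, and the allele is not described in the labels, so whether its transcript should fall is not known. Directions below are for the library labelled Chd2+/- against the library labelled Chd2+/+. Other family members were also close: Chd5 was 1.12-fold higher (95% interval 1.10 to 1.15), Chd3 was 1.11-fold higher and Chd8 was 1.10-fold lower in the library labelled Chd2+/-.

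Among genes with an established symbol, at least 1 FPKM in either library and the same direction in FPKM, the 12 highest and 12 lowest by log2 fold change in the authors' deposited table were of varied function. Cipc, an inhibitor of the circadian CLOCK protein, rose 8.25-fold (95% interval 7.26 to 9.40), from 1.99 to 16.4 FPKM, in the library labelled Chd2+/-. Fignl1, which takes part in homologous recombination, rose 5.79-fold (5.07 to 6.63), and Hsd3b6, a steroidogenic dehydrogenase, rose 5.68-fold (5.22 to 6.20), to 71.0 FPKM. Zscan2, a zinc-finger gene, fell 7.07-fold (6.29 to 7.97), from 30.0 to 4.24 FPKM, and Scand1 fell 5.26-fold (4.54 to 6.11), from 58.6 to 11.1 FPKM. Tbx3, a T-box transcription factor, fell 3.73-fold (2.68 to 5.29) from a low level of 1.01 FPKM, and Mef2d fell 3.59-fold (3.10 to 4.16).

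The authors' deposited table holds 422 genes, 214 higher and 208 lower in the library labelled Chd2+/-. In the authors' deposited table the adjusted p was 3.24e-282 for Cipc, 5.64e-280 for Zscan2 and 7.83e-17 for Tbx3, and a test on the fragments of 2 libraries compares those libraries, not the genotypes. By that filter, the others highest in the authors' deposited table, by log2 fold change, were Ugt1a6b at 4.70, Adat3 at 2.74, Wdr74 at 2.72, Gtf2ird2 at 2.23, Styx at 2.13, Mum1l1 at 2.06, Zfp346 at 2.03, Fcmr at 1.95 and Angptl7 at 1.89. By the same filter, others among the lowest in the authors' deposited table were Gprasp2 at -4.14, Pced1b at -2.83, Lrg1 at -2.78, Fam109b at -2.44, Vps51 at -2.21, Abi3 at -2.05 and Scamp4 at -1.87. Several of these share exon positions with another detected gene and are uncertain for that reason: Ugt1a6b with Ugt1a1, Ugt1a7c and other Ugt1a genes, Adat3 with Scamp4, Vps51 with Tm7sf2, Gprasp2 with Bhlhb9, Pced1b with Amigo2, Scand1 with Cnbd2, Gtf2ird2 with Ncf1, Styx with Gnpnat1, Fam109b with Smdt1, Abi3 with Gngt2, Phospho1 and Zfp652, and Mef2d with 1700113A16Rik. The same holds for Chd8, Gfra1, Sycp3, Col3a1, Insl3, Cyp11a1, Upf1 and Casp9. Adat3 and Scamp4 moved in opposite directions, as did Tm7sf2 and Vps51.

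**Figure D1:**
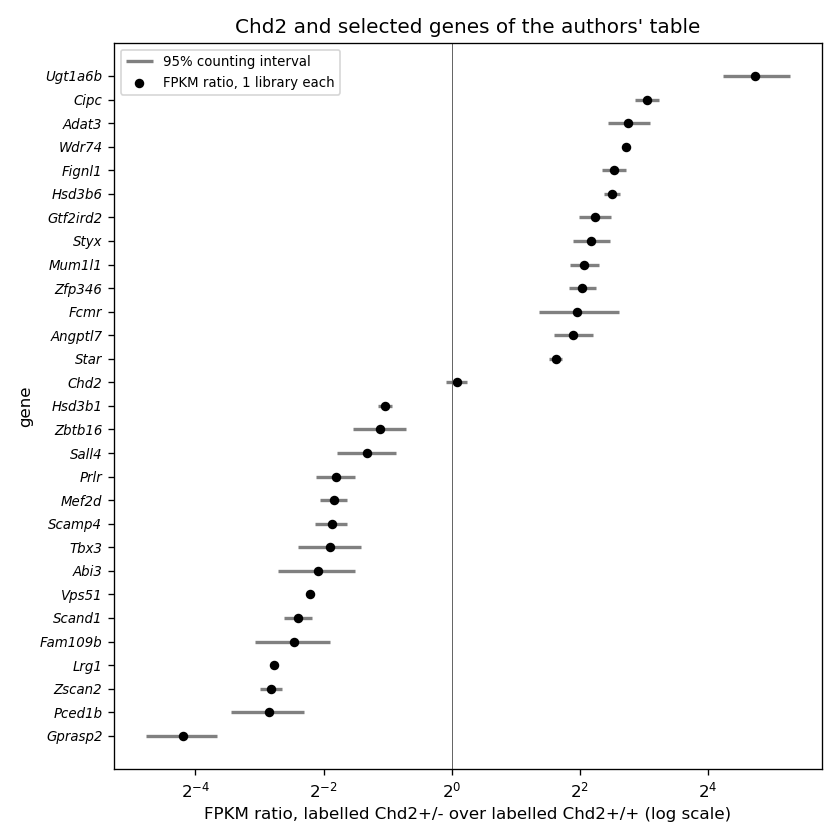
Ratio of FPKM in the library labelled Chd2+/- to that in the library labelled Chd2+/+ (log axis) for Chd2, genes among the highest and lowest chosen from the authors' deposited table, and Star, Hsd3b1, Prlr, Zbtb16 and Sall4; points are 1 library over 1 library and bars are 95% counting intervals, drawn where whole fragments were recovered. Chd2 lies at 1.05, while Cipc lies at 8.25.

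By size alone, among 15560 genes with at least 1 FPKM in either library, 137 were at least 2-fold higher and 173 at least 2-fold lower in the library labelled Chd2+/- on log2(FPKM + 1), a scale that understates the difference of low genes. Of these, 62 of the higher and 60 of the lower genes are in the authors' deposited table, whose 422 genes were all at least 2-fold apart on plain FPKM. Kctd12 was among the others, with 574 fragments in the library labelled Chd2+/- and 0 in the library labelled Chd2+/+, at least 212-fold higher against a floor of 3 fragments per library; it shares exon positions with the antisense gene Gm26778 and was chosen after its values were seen. Every gene of the authors' deposited table with whole fragments in both libraries, 404 in all, had at least 27 in each. Rescaled to TPM, which moved the median of all genes by -0.11 on the log2 scale and also made the pseudocount smaller beside each value, the counts were 191 higher and 402 lower, and the share of higher genes went from 44.2% to 32.2%. Scaling by the sum of whole fragments was chosen after seeing the data. It moved the median about as far and gave 115 higher and 249 lower, a share of 31.6%. That sum was 24296523 against a scaling total of 25180100 in the library labelled Chd2+/-, and 24623291 against 27907876 in the library labelled Chd2+/+. The shift came from this unequal shortfall, so this setting is no separate check of the TPM counts. At a cut of 1.5-fold on the main scale the balance turned, with 798 higher and 687 lower.

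Spermatogonial markers were lower in the library labelled Chd2+/-. Markers of undifferentiated spermatogonia, the population that holds the stem cells, had a list median of -0.39 (percentile 0.18 among random lists). The 12 markers at the floor of 1 FPKM lay below 0 on the log2 scale, and without the floor 18 of 24 detected markers did (percentile 0.20). The 6 detected markers above 0 were under the floor, while Zbtb16, Sall4, Egr4 and Nanos3 reached it only in the library labelled Chd2+/+. Zbtb16, a transcription factor needed for stem cell maintenance, fell 2.17-fold (95% interval 1.64 to 2.91), from 171 to 71 fragments, and Sall4 fell 2.50-fold (1.83 to 3.45), from 155 to 56 fragments. Both are in the authors' deposited table, with log2 fold changes of -1.11 and -1.30, and no other member is. Of the random lists, 6.07% held as many genes of that table. Egr4 had 25 fragments against 82, and Nanos3 had 7 against 28. Gfra1, a receptor for the niche factor GDNF, stayed under the 1 FPKM floor and was 1.16-fold higher (0.884 to 1.52), a difference not detectable at this depth. Id4 had 7.44 FPKM against 12.5 FPKM, and Etv5 had 7.83 against 8.20 FPKM.

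Differentiating spermatogonia followed, with 10 of 12 measured markers lower in the library labelled Chd2+/- and a median of -0.27 (percentile 0.52); none is in the authors' deposited table. Stra8, the retinoic-acid-responsive gene of meiotic entry, had 4.87 FPKM against 9.24 FPKM, and Sohlh1 had 2.22 against 4.28 FPKM. Kit, the receptor that marks this stage, was 1.16-fold lower (95% interval 1.04 to 1.31). With the trend with GC content removed, a setting chosen after seeing the data, this list was inside the random range at percentile 2.54.

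Among later germ cells only the elongating spermatid list lay outside its range. Elongating spermatid genes were higher in the library labelled Chd2+/-, 23 of 26, with a median of 0.49, above all 10000 random lists; none is in the authors' deposited table. Cabs1 was 1.81-fold higher (95% interval 1.76 to 1.86), Akap4, a fibrous sheath protein of the sperm tail, 1.72-fold higher, Smcp 1.67-fold higher and the protamine Prm1 1.41-fold higher (1.40 to 1.42). Round spermatid genes had a median of 0.25, with 24 of 27 higher, and lay inside the random range at percentile 97.2. They passed it with no filter on low values (98.4), without genes that share exon positions (97.6) and against unmatched lists (99.9). Acrv1, an acrosomal protein gene, was 1.22-fold higher (1.16 to 1.27). Pachytene and later spermatocyte genes (percentile 82.1), the meiotic prophase machinery (31.1) and flagellar genes (89.1) lay inside the range, with Sycp3, of the synaptonemal complex, at 60.4 against 66.8 FPKM and Rec8 at 33.0 against 27.2 FPKM. The meiotic list lay below the range with the GC trend removed (2.39), and the flagellar list lay above it against unmatched lists (97.8).

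Somatic cell markers went in different directions. Sertoli cell markers were lower in the library labelled Chd2+/- for 22 of 25 genes, with a median of -0.33 (below all random lists). Drd4 fell 2.64-fold (95% interval 2.24 to 3.14), the 1 Sertoli list member in the authors' deposited table. Cst12 had 75.2 against 127 FPKM, Amh 1.81 against 3.20 FPKM, and Sox9, the Sertoli lineage factor, 2.85 against 3.62 FPKM. Macrophage and antigen presentation genes had a median of -0.33 (percentile 0.01), and H2-Eb1, an MHC class II gene, and Fcer1g, an Fc receptor subunit, fell, with log2 fold changes of -1.52 and -1.09 in the authors' deposited table. Fibroblast and matrix genes had a median of 0.27 (percentile 99.8), with Col3a1 1.47-fold higher and Dcn 1.44-fold higher; with no filter on low values the list was inside the range (median 0.13, percentile 96.4). Peritubular myoid (84.2) and endothelial (77.6) lists lay inside the range, and Acta2 had 41.3 against 35.2 FPKM. Globin genes of the erythroid list were lower, with Hbb-bs at 11.6 against 20.6 FPKM and a list median of -0.62 over 5 members, below all random lists. The lymphocyte and interferon lists were too small to place; Cd3d had 106 against 117 fragments, and Isg15 had 8 against 30.

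Steroidogenic genes split. Star, which carries cholesterol into mitochondria, rose 3.08-fold (95% interval 2.86 to 3.31), from 8.62 to 26.6 FPKM, and Hsd3b6 rose as above. Hsd3b1 fell 2.07-fold (1.92 to 2.23), from 43.9 to 21.3 FPKM, and Prlr, the prolactin receptor, fell 3.51-fold (2.85 to 4.34). These 4 of the 17 measured members are in the authors' deposited table, and 0.02% of random lists held as many. For every other list with a measured member in that table the share was larger. It ran from 5.62% (macrophage and antigen presentation) to 62.0% (oxidative phosphorylation). Hsd3b1 and Hsd3b6 are paralogs, so the division of fragments between them is uncertain. The Leydig list had a median of -0.20 (percentile 1.04), inside the range at 5 FPKM (11.7) and without genes that share exon positions (19.0). Insl3, the most abundant member, had 652 against 748 FPKM and Cyp11a1 32.5 against 32.4 FPKM. Cholesterol synthesis genes were higher, 16 of 21, with a median of 0.21 (percentile 99.2; 93.6 at 5 FPKM). Insig1 had 8.87 against 4.56 FPKM and Sc5d 5.44 against 2.78 FPKM, while Tm7sf2 rose, with a log2 fold change of 1.51 in the authors' deposited table.

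Adipose genes were higher in the library labelled Chd2+/-, with a median of 0.95 over 6 measured members, 5 of them above 0, and above all random lists. None of the 6 is in the authors' deposited table, whose genes with whole fragments had at least 27 in each library. Cfd, Car3, Fabp4 and Retn had fewer in the library labelled Chd2+/+, and Adipoq and Cidea were under 2-fold apart. Lpl, a lipase under the floor at 0.678 against 0.154 FPKM, is in that table, with a log2 fold change of 2.07. Cfd, the adipokine adipsin, had 300 fragments against 0, at least 111-fold higher against the floor of 3 fragments per library. Car3 had 190 against 0, at least 70.2-fold higher, and Fabp4, a fatty acid carrier of fat cells, had 177 against 10, 19.6-fold higher (95% interval 10.4 to 41.6). Adipoq had 180 against 113 fragments, while Cidea was 1.41-fold lower, at 5.87 against 8.25 FPKM, with no counting interval. The epididymis list had only 2 measured members, Rnase10 at 189 against 180 fragments and Defb21 at 23 against 20.

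Most ribosomal protein and oxidative phosphorylation genes were lower in the library labelled Chd2+/-. Of 83 ribosomal protein genes 80 were lower, with a median of -0.30, and of 92 oxidative phosphorylation genes 84 were lower, with a median of -0.21, both below all random lists. Rpl39 fell 2.02-fold (95% interval 1.75 to 2.33), and Rpl29, at 49.7 against 29.0 FPKM, went the other way. Ndufaf4, a complex I assembly factor caught by the name pattern of the list, rose 2.32-fold (1.74 to 3.12). Canonical histone genes had a median of -0.26 (percentile 0.02; 10.5 without genes that share exon positions). Mitochondrially encoded genes were barely outside the range, with a median of -0.08 (percentile 2.43), and were inside it under several settings, such as 21.0 against unmatched lists. Among them mt-Nd4l had 2 fragments against 3384, 1527-fold lower (422 to 12611), and shares exon positions with mt-Nd4, so its value is uncertain.

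Apart from the canonical histone list given above, the lists of chromatin and mRNA decay genes lay inside the random range. These are transcript levels of such genes. They measure neither chromatin nor mRNA stability, which the series title names. Percentiles were 54.9 for the chromodomain helicase family, 59.9 for histone modifiers, 10.4 for other chromatin remodellers and 48.8 for mRNA decay and deadenylation; none of their members is in the authors' deposited table. Prmt1, an arginine methyltransferase, had 8.08 against 15.0 FPKM in the library labelled Chd2+/+, Kdm3a had 23.6 against 16.8 FPKM, and Upf1, of nonsense-mediated decay, 23.3 against 33.5 FPKM. The DNA damage (46.9), p53 and apoptosis (19.3), cell cycle (3.60), immediate early (7.08), piRNA (8.54) and niche signalling (61.6) lists were also inside. Casp9, of the apoptosis list, fell 2.05-fold (95% interval 1.71 to 2.47). With the GC trend removed the piRNA list was below the range (0.18), and without genes that share exon positions the cell cycle list was (2.38). In all, 14 of 30 lists lay outside their range, against 1.5 expected by chance if the genes of a list varied independently. Genes of a list can move together, so the number expected can be higher.

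**Figure D2:**
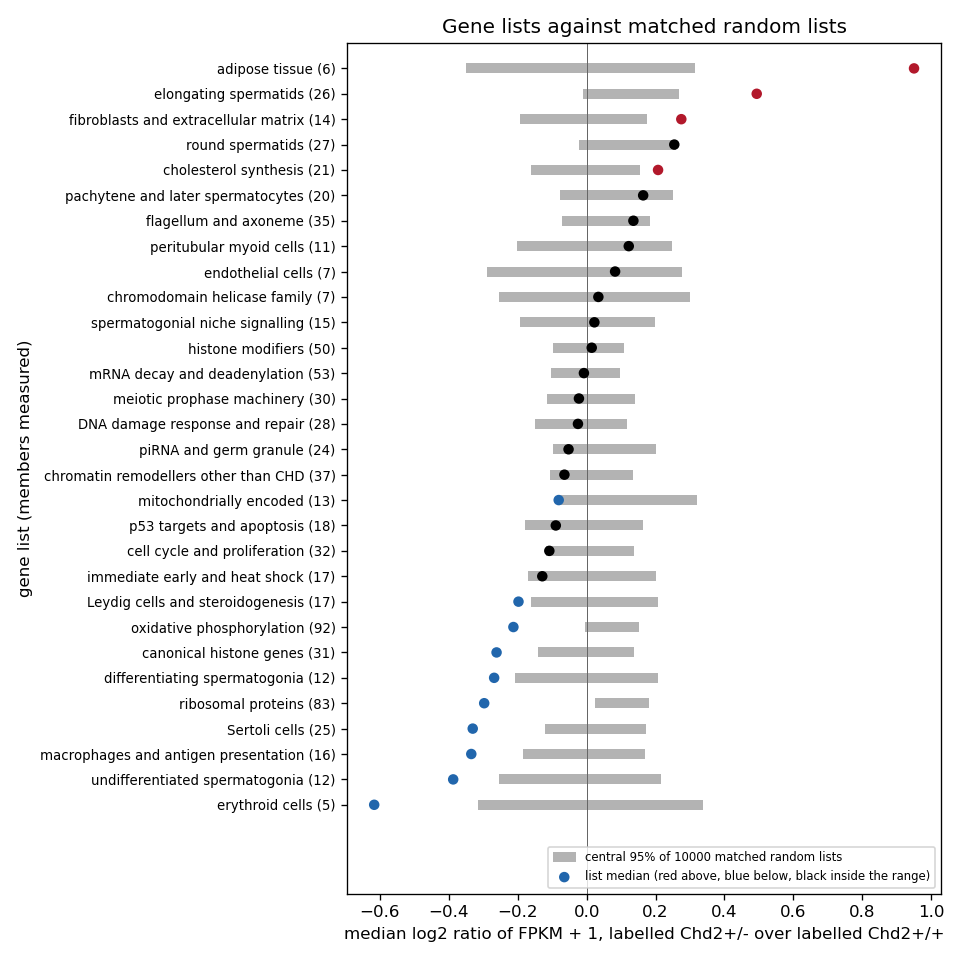
Median log2 ratio of FPKM + 1, library labelled Chd2+/- over library labelled Chd2+/+, for each of 30 gene lists (points; number of measured members in parentheses), with the central 95% of 10000 expression-matched random lists as grey bars. Elongating spermatid genes lie at 0.49 and Sertoli cell genes at -0.33, both outside their grey bars.

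By chromosome, genes of the Y chromosome were higher in the library labelled Chd2+/- (168 genes, median 0.38) and those of the X chromosome slightly so (637 genes, median 0.08), both above all random lists. The Y list was inside the range at 5 FPKM (percentile 90.1), and many Y genes are multicopy, so their values are uncertain. Chromosome 17 lay lowest among the autosomes at -0.07. In all 12 of 22 chromosomes lay outside their range, against 1.1 expected by chance if their genes varied independently. Of these 12, 6 stayed outside on the same side with the GC trend removed. Chromosome 7, which carries Chd2, lay inside its range (percentile 3.06) and passed below it under several settings, such as 0.67 at 5 FPKM.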

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

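Scaling by the sum of whole fragments and the GC correction were chosen after seeing the data. So were the restriction to protein-coding genes and the removal of genes that share exon positions. The counts of genes at least 2-fold higher and lower, 137 and 173, became 379 and 435 with a pseudocount of 0.1, 423 and 477 with 0.01, 66 and 80 at 5 FPKM, 798 and 687 at 1.5-fold (where higher genes outnumber lower ones), and 66 and 68 among protein-coding genes; smaller pseudocounts shrink low genes less, and the other settings change by construction which genes can count. The lower count became 402 with TPM and 109 without genes that share exon positions. Scaling by the sum of whole fragments gave 115 higher and 249 lower, so 31.6% were higher. No filter on low values changed neither count, because a 2-fold difference on this scale needs 1 FPKM. Of the 214 higher and 208 lower genes of the authors' deposited table, all were at least 2-fold apart on plain FPKM. As every gene there has an absolute log2 fold change of at least 1.00, this was close to fixed beforehand. On log2(FPKM + 1), the main scale, on which the pseudocount shrinks low genes, 62 and 60 were at least 2-fold apart. With the GC trend also removed 49 and 53 were. Applying that scale to these genes was added after seeing the data. An adjusted p under 0.01 removed none, because no gene of that table had a larger one. The number of lists outside their range, 14, stayed between 10 and 15, and that of chromosomes, 12, between 8 and 14. Among single lists and settings 336 calls stayed, 11 were lost and 7 were gained. Among chromosomes 186 stayed, 19 were lost and 15 were gained, and none of either kind turned to the other side. Settings that rescale a library (same median ratio, TPM, sum of whole fragments) move a list and its random lists nearly together. Each kept all 30 list calls, which could hardly have changed, so those calls say little about robustness. Of the named genes' log2 ratios, 593 values stayed within their counting interval and 265 did not, and a further 90 belong to genes without an interval. None of the named genes in the authors' deposited table changed sign, and the other genes of that table were not checked for this. Medians of columns and leaving out a column were not run, as each genotype has 1 column. No paired analysis was possible because each genotype has 1 sample. Depth limits genes with few fragments, such as Nanos3.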

Other observations

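The tests in this part were chosen after the result was seen, except the removal of the length trend and the search for near-identical copies, which were written down before their results. Among 42 genes with at most 3 fragments in 1 library and at least 40 in the other, 25 were near absent in the library labelled Chd2+/+ and 17 in the library labelled Chd2+/-. Pcdhgb8, a clustered protocadherin, had 969 fragments in the library labelled Chd2+/- against 2, and Ugt1a1, a glucuronosyltransferase, had 128 against 0. In the other direction, Gm26689 had 0 against 164 and Pdxp, a pyridoxal phosphatase, 0 against 62. Hp, the haptoglobin gene, had 131 against 0, and Cyp2e1 had 71 against 2. Genes with higher transcript GC content had lower ratios in the library labelled Chd2+/-: across genes, which are not independent replicates, Spearman's rho was -0.25. The median GC content was 46.6% for genes higher and 52.9% for genes lower in the authors' deposited table.

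Elongating spermatid genes were higher in the library labelled Chd2+/-, while spermatogonial, Sertoli, ribosomal protein and oxidative phosphorylation genes were lower. More spermatid RNA that dilutes every other cell type alike would not part the somatic lists. The fibroblast list median lay 0.61 above the Sertoli list median on the log2 scale (central 95% of random pairs -0.28 to 0.20). The myoid median lay 0.45 above the Sertoli median (-0.29 to 0.26). With no filter on low values these gaps were 0.41 (-0.23 to 0.17) and 0.40 (-0.23 to 0.22). In that setting the fibroblast list by itself fell inside its range at percentile 96.4. The somatic lists thus did not move alike in these libraries. However, they were paired after the Sertoli list was seen to lie below all random lists, so wide gaps were likely beforehand. The comparison therefore does not decide on dilution, which stays open. With the GC trend removed 13 of 14 lists stayed outside on the same side, and differentiating spermatogonia were the exception. The elongating spermatid, undifferentiated spermatogonia, Sertoli, ribosomal protein and oxidative phosphorylation lists were among those that stayed. This argues against GC content as the whole source for those lists. It does not exclude a part, since the meiotic (percentile 2.39) and piRNA (0.18) lists then passed below their range. With the trend with exon length removed 14 of 14 stayed, but this trend was nearly absent (rho 0.04), so nothing follows for a length bias, which stays open. Fat could bring stromal and matrix RNA to the fibroblast list, and a change in the makeup of the tissue piece and an effect of the genotype both stay open, since each genotype has 1 library and Chd2 was not lower in the library labelled Chd2+/-.

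Adipose genes, most of them absent or scarce in the library labelled Chd2+/+, may come from fat on the tissue of the library labelled Chd2+/-. Of 12 adipose list members with at least 10 fragments in either library, 11 were higher there beyond counting error, among them Lpl with 179 fragments against 45, Plin1 with 88 against 60 and Cidec with 33 against 0. Reads shared with an overlapping gene are argued against, since only 1 of the 11, Plin4, shares exon positions with another detected gene. The remaining member, Cidea, was 1.41-fold lower, from a level of 8.25 FPKM in the library labelled Chd2+/+ that would hide a small share of fat, so fat stays open rather than shown. An effect of the genotype stays open as untested, and Adipoq and Plin1 had fragments in the library labelled Chd2+/+ as well.

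The genes near absent in 1 library may in part reflect how reads were divided among genes of shared sequence. Fragments of the overlapping or matching genes were not compared, so such a division was not tested directly. An exon overlap with another detected gene was present for 45.2% of the near-absent genes, against 9.52% to 33.3% in the central 95% of matched random sets. At least 50% of the sequence was found, as words of 75 bases, in a transcript of another gene for 65.9% of the 41 searched, against 2.38% to 21.4%. Neither held for 9 genes, which include Cfd, Car3, Hp and Cyp2e1, so those differences stay without this explanation. An effect of the genotype on the others was not tested.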
